A study of Homo sapiens with 8 samples.

How the data were processed

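Total RNA of SH-SY5Y cells was extracted with an RNeasy Plus kit and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The design text names the HiSeq2500. The submitters' processing notes name Trimmomatic 0.30, STAR 2.4.2a, edgeR 3.10.5 and the build hg19. Their settings, their roles and the annotation are not given in the sources used here.

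The authors deposited 1 file of raw counts per library, with 57820 Ensembl genes after 4 summary rows, in the layout of STAR's gene counts. Each file holds counts made without regard to strand, counts on the strand of the read and counts on the opposite strand. Nearly all gene reads fell in the opposite-strand column, so that column was used. The summary rows (unmapped, multiply mapped, in no gene, ambiguous) held 37.1% to 58.9% of the reads and stayed out of library sizes and tests. Reads mapping to several places were not assigned to a gene, which lowers genes with near-identical copies. Gene names, types and coordinates come from GENCODE release 44 mapped to GRCh37, the same assembly as hg19. Of the IDs, 55538 matched by their unversioned form, as did 16850 of the 17331 genes tested.

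Groups were taken from the sample titles, with 2 libraries in each of siCTR, siSETD8, DMSO and UNC0379. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15) and scaled by TMM. One quasi-likelihood model with 1 coefficient per group was fitted over all 8 libraries in edgeR 4.0.16 (R 4.3.3), which leaves 4 residual degrees of freedom. The contrasts were siSETD8 against siCTR, UNC0379 against DMSO, the difference of these responses, and DMSO against siCTR. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold. Standard errors are the fold change divided by the root of the F statistic. CPM values are scaled by TMM and given as mean ± SD. The typical spread between libraries of a group was 17.5% (biological coefficient of variation).

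Before the data were examined, 25 gene lists were fixed, of which 24 had tested members. The list of immune and endothelial markers had 0, and its highest level was 0.59 CPM. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the lists of a contrast, with camera under an estimated correlation and fry beside it. No list kept its call with an estimated correlation in any contrast. Correlation alone does not account for this, since camera then also uses the 4 residual degrees of freedom. For p53 apoptosis targets after siSETD8 the estimated correlation was -0.017, yet the unadjusted camera p went from 0.00018 to 0.016. Fry asks whether a list moves on balance one way and does not compare it with other genes. List members without a match numbered 5.

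The genes named were set by a rule before the data were examined. It takes SETD8, MDM2, CDKN1A, BBC3, MYCN, MYC and 1 gene that is not reported here, the 8 largest changes per direction and comparison and the 5 largest per direction of the difference. These had to pass the test, reach a mean of 2 CPM, show no overlap between groups and have a symbol of their own. Genes of chromosome Y, XIST and TSIX were also left out, which the rule did not state. This dropped TSIX, called after siSETD8 with a larger rise (log2 fold change 5.79) than any gene named there. Its reads were 0 and 5 in siCTR and 161 and 91 after siSETD8. The rule also takes the 3 members with the smallest adjusted p of each list that passed camera or held 3 calls. Genes named in addition are said to be so.

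After the changes were seen, 3' UTRs were searched for 7-mers. The longest annotated UTR of each coding gene (at least 50 bases) was used, KMT5A left out. The log2 fold change, limited to 2 in size, was regressed on presence of each 7-mer, given UTR length and GC content, for 16346 7-mers present in at least 50 genes (Python 3.11.15, numpy 2.4.6). The search was also split, with the 7-mer picked in 1 siSETD8 and 1 siCTR library and measured in the other 2, on differences of log2(CPM + 1). The siRNA sequences are not given in the sources used here.

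The steps were tested on simulated data drawn from the real means, library sizes and dispersions. For siSETD8 over 16909 genes, the model recovered 52.0% of genes changed 2-fold and 88.7% of those changed 4-fold, with 10 false calls among 158. For UNC0379 it recovered 45.7% and 80.4%, with 6 false calls among 127. Camera called a list shifted by 0.7 on the log2 scale and no other. The simulated genes were drawn independently, whereas the correlation estimated in the real data was 0.23 for p53 targets and 0.74 for mitosis. The simulation therefore cannot show whether camera with the preset correlation avoids false calls here. In the 7-mer step over 12485 genes, 10 of 10 planted 7-mers ranked first. The planted log2 shift was -0.3, in rarer 7-mers, against -0.16 for the 7-mer reported below, so a weaker effect was not simulated.

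The alternatives were limma-voom, DESeq2 1.42.0, other scalings, other count filters, each comparison's own 4 libraries, the replicate number as a block, a fold minimum, and leaving out each library. Chosen after seeing the data were counts without regard to strand, a GC and length correction, the share of reads in no gene as a covariate, genes without an opposite-strand gene, and genes without the 7-mer.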

Results

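RNA from SH-SY5Y cells, an established human neuroblastoma line that the labels call SY5Y and describe as wild type for MYCN, was sequenced in 8 libraries. SETD8, whose current symbol is KMT5A, is the enzyme that places a single methyl group on lysine 20 of histone H4. It was silenced with an siRNA (siSETD8, 36 h) or inhibited with the compound UNC0379 (4 µM, 12 h). An siRNA control (siCTR) and the solvent DMSO served as the controls, and each of the 4 groups held 2 libraries. The times of the siCTR and DMSO cells are not stated, so the fold changes assume controls of the same time. The series addresses whether loss of SETD8 activity reactivates p53 in neuroblastoma cells. Reads assigned to genes numbered 20933439 and 18400881 in the siCTR libraries, 16693415 and 16425693 after siSETD8, 27905701 and 25581440 with DMSO, and 27398284 and 18501414 after UNC0379. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Replicates differed by more than counting noise in each group, and the least alike were the UNC0379 libraries (correlation of log CPM across genes 0.979, against 0.986 to 0.988 in the other groups). UNC0379 replicate 2 lay at -68.7 on the second principal component, and the other 7 libraries between -15.3 and 28.8.

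SETD8 RNA itself was low only in the libraries labelled siSETD8. KMT5A (ENSG00000183955.8, GRCh37 chromosome 12, 123868679 to 123893900) stood at 74.6 ± 6.02 CPM in siCTR and 11.5 ± 2.27 CPM after siSETD8 (SD, n = 2 each), which left 15.4% of the control level. The log2 fold change was -2.69 (SE 0.20, adjusted p = 0.000342, edgeR quasi-likelihood test). With DMSO it stood at 64.4 ± 2.44 CPM and after UNC0379 at 69.6 ± 11.6 CPM, a log2 fold change of 0.11 (SE 0.18, adjusted p = 0.80, edgeR).

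Silencing of SETD8 was followed by higher RNA of p53 targets. CDKN1A, which encodes the cell cycle inhibitor p21 (ENSG00000124762.9, chromosome 6, 36644237 to 36655114), rose from 97.6 ± 43.2 to 377 ± 36.4 CPM (SD, n = 2 each), a log2 fold change of 1.95 (SE 0.36, adjusted p = 0.024, edgeR). MDM2, the ubiquitin ligase that degrades p53 (ENSG00000135679.17, chromosome 12, 69201957 to 69239324), rose from 247 ± 29.5 to 444.3 ± 12.0 CPM, a log2 fold change of 0.85 (SE 0.17, adjusted p = 0.033, edgeR). BTG2, an antiproliferative gene, rose from 18.5 ± 3.88 to 72.1 ± 2.15 CPM, ZMAT3, an RNA-binding protein gene, from 159 ± 24.5 to 535 ± 68.9 CPM, and SESN2, a stress-induced regulator of mTORC1, from 13.8 ± 1.11 to 40.3 ± 4.69 CPM. The secreted stress factor GDF15 rose from 9.41 ± 2.03 to 39.6 ± 8.97 CPM. BTG2 kept its call under every alternative, while CDKN1A lost it in 4 of 23 (lowest log2 fold change 1.57) and MDM2 in 7 of 22 (lowest 0.66).

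Of 53 p53 targets tested, 21 rose, none fell and 32 did not pass (33 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 0.77. The list rose against all other genes (camera, adjusted p = 1.3e-16), with adjusted p = 0.41 with an estimated correlation and 0.020 by fry. Among 16 p53 targets with roles in apoptosis, 4 rose and none fell (7 higher and 2 lower adjusted over the list alone). This list shares members with the p53 target list, among them FAS, TP53INP1, TNFRSF10B and BBC3, so its result is not separate evidence. The death receptor gene FAS rose by a log2 fold change of 2.05 (SE 0.37), TP53INP1 by 1.12 (SE 0.21) and the death receptor gene TNFRSF10B by 1.00 (SE 0.19). BBC3, which encodes PUMA, was at 12.9 ± 2.88 and 20.7 ± 1.25 CPM and did not pass (adjusted p = 0.32, edgeR). The apoptosis list gave adjusted p = 0.00071 with camera, adjusted p = 0.38 with an estimated correlation and 0.013 by fry, and lost the camera call among genes without an opposite-strand gene (median 0.43, adjusted p = 0.68). That setting tests 8217 genes and leaves out FAS, TP53INP1, TNFRSF10B and BBC3. The call was therefore lost on a shorter list, which does not show that strand produced it.

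Cell cycle genes were lower as groups after siSETD8, while few single members passed. Of 40 mitosis genes, 38 had a negative log2 fold change, with a median of -0.47 (camera, adjusted p = 5.9e-09). Only ECT2, a cytokinesis factor, fell, from 146 ± 1.74 to 76.4 ± 8.22 CPM, and 11 members were lower adjusted over the list alone. Of 39 DNA replication genes, 2 fell, with a median of -0.38 (camera, adjusted p = 4.3e-05). These were the transcription factor gene E2F1 (log2 fold change -1.14, SE 0.20) and the helicase subunit gene MCM4 (log2 fold change -1.07, SE 0.24). None of the 10 replication-dependent histone genes passed over all genes, 9 were lower adjusted over the list alone, and the median was -0.77 (camera, adjusted p = 4.3e-05). With an estimated correlation these lists had adjusted p = 0.55 for mitosis, 0.65 for DNA replication and 0.55 for histones, and by fry 0.19, 0.33 and 0.19. Reads in no gene made up 22.6% and 30.5% of the siSETD8 libraries and 16.3% and 21.5% of siCTR. With that share as a covariate, chosen after seeing the data, DNA replication lost the camera call (median -0.011, adjusted p = 0.74), and mitosis (median -0.23, adjusted p = 0.023) and histones (median -0.63, adjusted p = 0.0068) kept it. The share was higher in both siSETD8 libraries than in siCTR, so a call lost with the covariate cannot tell read composition from the treatment.

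Smaller shifts were found in 3 further lists. Lysosome genes were lower (median -0.27, camera adjusted p = 0.016), with 1 of 27 falling, the protease gene CTSL (log2 fold change -0.92, SE 0.20), and the call was lost among genes without the 7-mer described below (median -0.28, adjusted p = 0.13). Immediate early genes were higher (median 0.28, camera adjusted p = 0.036), with 1 of 18 rising, the transcription factor gene EGR1 (log2 fold change 1.44, SE 0.29). Their call was lost without siCTR replicate 2 (median 0.20, adjusted p = 0.10), siSETD8 replicate 1 (median 0.22, adjusted p = 0.092) or siSETD8 replicate 2 (median 0.30, adjusted p = 0.080). MYC targets and ribosome biogenesis genes were lower (median -0.20, camera adjusted p = 0.041), with none of 30 passing. This call held in 13 of 22 alternatives and was lost, for example, without siCTR replicate 1 (median -0.17, adjusted p = 0.41) and with the covariate (median -0.015, adjusted p = 0.74). With an estimated correlation these had adjusted p = 0.41, 0.41 and 0.72, and by fry 0.044, 0.013 and 0.35. The 13 transcripts encoded by mitochondrial DNA had a median of 1.55 (camera, adjusted p = 2.8e-05, and adjusted p = 0.55 with an estimated correlation and 0.19 by fry). It was 0.84 without siSETD8 replicate 2 and 0.78 with the covariate, where the camera call held. Their share of gene reads was 3.0% and 4.76% in the siSETD8 libraries and 2.02% and 1.63% in siCTR. MYCN (log2 fold change 0.57, adjusted p = 0.28) and MYC (log2 fold change -0.61, adjusted p = 0.19) did not pass in edgeR.

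Over 17331 genes tested, 224 rose and 186 fell after siSETD8 (edgeR, adjusted p under 0.05), and 3199 had an unadjusted p under 0.05, where 867 are expected by chance. The largest falls besides KMT5A were in TNR, a matrix glycoprotein gene of the nervous system (26.8 ± 1.79 to 3.38 ± 0.14 CPM), and HRAS, the small GTPase gene (ENSG00000174775.12, chromosome 11, 532242 to 537321), which fell from 32.2 ± 1.84 to 5.28 ± 0.34 CPM (log2 fold change -2.61, SE 0.19, adjusted p = 0.000342, edgeR). PYGL, which encodes liver glycogen phosphorylase, TSPAN12, PPIC, DYNLT3 and COMMD6 fell by log2 fold changes between -2.18 and -2.09. The 3' UTRs of 119 of the 174 genes that fell and had a UTR to search held the 7-mer GGAAGGA, against 43 of 161 genes that rose and 25.9% of all 12485 genes searched. The 7-mer was picked on these same fold changes, so these shares describe the genes and test nothing. The SETD8 transcript holds this 7-mer in its coding sequence, as it holds 3358 of the 16346 7-mers searched. The UTRs of HRAS and TNR held 6 copies each and those of DYNLT3, ECT2, E2F1, MCM4 and CTSL 1 each, while PYGL, TSPAN12, PPIC and COMMD6 held 0.

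Among the largest rises, NOTCH1, a receptor of cell fate signalling, went from 1.98 ± 0.39 to 19.4 ± 7.47 CPM, the adhesion receptor gene ADGRG1 from 0.78 ± 0.11 to 9.69 ± 1.80 CPM and NECTIN4, an adhesion molecule gene, from 0.64 ± 0.16 to 5.25 ± 1.36 CPM. The calls of RPL30-AS1, TUBA1B-AS1, MVP-DT, ST6GALNAC2 and BEST1 rested on strand. Their log2 fold changes were between 3.06 and 5.23 in the stranded counts and between 0.11 and 0.43 in counts made without regard to strand, where none passed. After UNC0379, ST6GALNAC2 was at 0.75 ± 0.06 CPM against 0.04 ± 0.05 with DMSO (log2 fold change 4.07). It did not pass there (adjusted p = 0.19, edgeR), and the others had log2 fold changes between 0.17 and 0.48. All 5 have an annotated gene on the opposite strand. The median share of wrong-strand reads over coding genes without such a neighbour was 3.13% and 1.14% in the siSETD8 libraries. It was 0.18% and 0.21% in siCTR. Whether the siSETD8 libraries were prepared in a separate batch cannot be told from the labels, and a batch effect would enter each siSETD8 fold change. Counts made without regard to strand gave 95 higher and 142 lower genes. Without siSETD8 replicate 2, 20 genes rose and 7 fell.

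**Figure D1:**
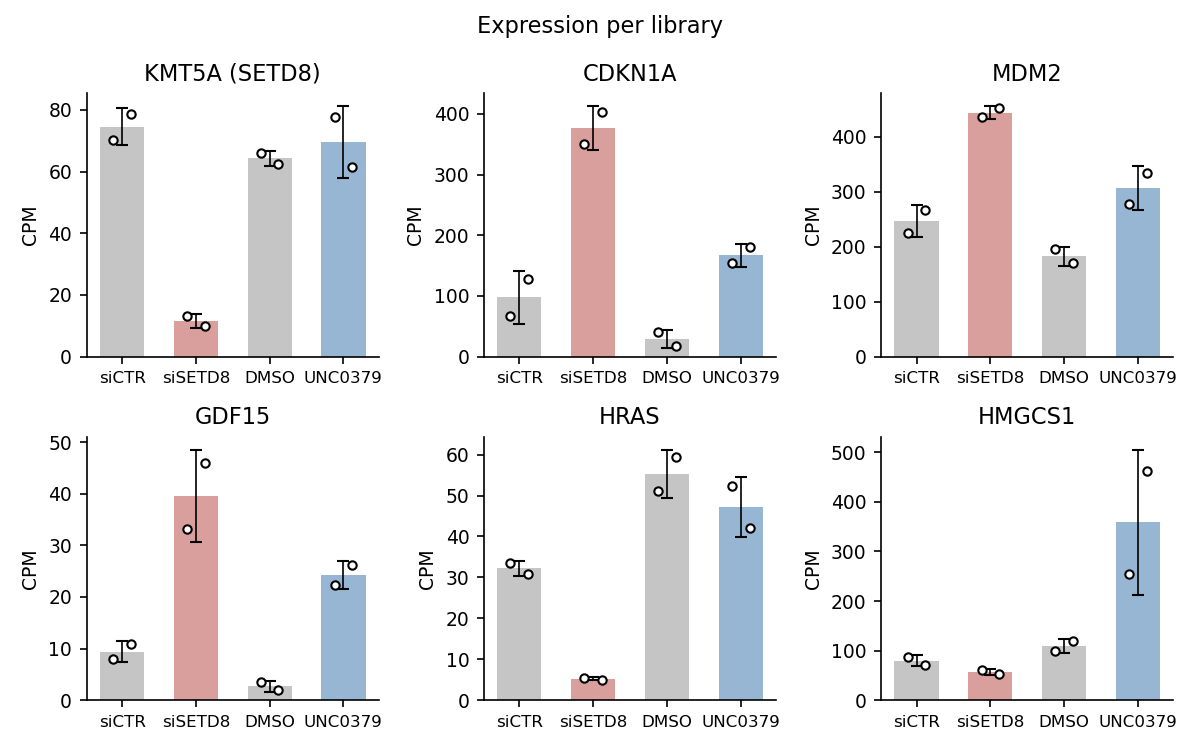
Expression in CPM (vertical axes from 0) of 6 genes in the 4 groups. Bars give the mean of 2 libraries, error bars the SD and circles the libraries. KMT5A and HRAS are low in both siSETD8 libraries, at 11.5 and 5.28 CPM on average, CDKN1A, MDM2 and GDF15 are higher in both treated groups than in their controls, and HMGCS1 is high in the UNC0379 libraries at 359 CPM on average.

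UNC0379 was followed by higher RNA of p53 targets as well. CDKN1A rose from 29.2 ± 15.4 to 167 ± 19.2 CPM (SD, n = 2 each), a log2 fold change of 2.52 (SE 0.37, adjusted p = 0.043, edgeR). GDF15 rose from 2.68 ± 1.09 to 24.2 ± 2.66 CPM (log2 fold change 3.17, SE 0.30, adjusted p = 0.0044, edgeR) and BTG2 from 6.49 ± 1.83 to 22.6 ± 2.41 CPM. The DNA damage recognition gene DDB2 rose from 19.8 ± 4.84 to 80.5 ± 35.3 CPM, the death receptor gene TNFRSF10A from 0.45 ± 0.12 to 4.71 ± 3.0 CPM and SPATA18, a mitochondrial quality control gene, from 1.57 ± 0.73 to 10.2 ± 4.84 CPM. MDM2 was at 183 ± 17.5 and 307 ± 39.6 CPM (log2 fold change 0.75, SE 0.17) and did not pass (adjusted p = 0.22, edgeR). BBC3 (log2 fold change 0.88, adjusted p = 0.33) did not pass in edgeR either.

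Of the 53 p53 targets, 6 rose and none fell after UNC0379 (35 higher and none lower adjusted over the list alone), and the median log2 fold change was 0.73. It was 0.45 without UNC0379 replicate 2 and 0.46 with the share of reads in no gene as a covariate (chosen after seeing the data), and the camera call held in both. The list gave adjusted p = 7.8e-20 with camera, adjusted p = 0.39 with an estimated correlation and 0.034 by fry. Of the 16 apoptosis targets, 1 rose (7 adjusted over the list alone), with a median of 0.32. This list gave adjusted p = 0.0063 with camera, adjusted p = 0.39 with an estimated correlation and 0.034 by fry. The apoptosis list's camera call was lost without UNC0379 replicate 1 (median 0.29), with no low-count filter (median 0.14, adjusted p = 0.066) and among genes without an opposite-strand gene (median -0.16, adjusted p = 0.79). The last setting leaves out TNFRSF10A, the 1 member that rose, and FAS, TP53INP1, TNFRSF10B and BBC3, so it tests a shorter list.

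Genes of cholesterol synthesis rose as a group after UNC0379. HMGCS1, which encodes the cytosolic HMG-CoA synthase (ENSG00000112972.10, chromosome 5, 43287572 to 43313614), went from 109 ± 14.8 to 359 ± 147 CPM (log2 fold change 1.71, SE 0.26, adjusted p = 0.043, edgeR). The sterol methyl oxidase gene MSMO1 went from 51.2 ± 6.41 to 131 ± 31.4 CPM (log2 fold change 1.35, SE 0.19, adjusted p = 0.043, edgeR). These were the 2 of 24 members that rose over all genes, 15 were higher adjusted over the list alone, and 22 had a positive log2 fold change, with a median of 0.80. The median over DMSO was 0.50 in UNC0379 replicate 1 and 0.99 in replicate 2, and the median log2 fold change was 0.49 without replicate 2, where the camera call held. Camera gave adjusted p = 1.3e-10, with adjusted p = 0.55 with an estimated correlation and 0.15 by fry.

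Other lists moved less after UNC0379 than the p53 target and cholesterol synthesis lists, with no member passing over all genes. Unfolded protein response genes (median -0.46), integrated stress response genes (median -0.41) and MYC targets and ribosome biogenesis genes (median -0.19) were lower, each with a camera adjusted p = 0.0016. Mitosis genes (median -0.26, camera adjusted p = 0.0016), NRF2 targets (median -0.21, camera adjusted p = 0.0063) and replication-dependent histones (median -0.33, camera adjusted p = 0.023) were lower too. Mitochondrial-encoded transcripts were higher (median 0.58, camera adjusted p = 0.00067). With an estimated correlation the adjusted p was 0.58 for mitosis and 0.55 for each of the other 6 lists. By fry the adjusted p was 0.33 to 0.44 over the 7 lists. The reads assigned to no gene made up 14.9% and 23.3% of the UNC0379 libraries and 11.4% and 10.8% of the DMSO libraries. With that share as a covariate, chosen after seeing the data, these 7 lists lost the camera call. The share was higher in both UNC0379 libraries than with DMSO, so the covariate also takes up part of any treatment effect. These losses therefore cannot tell read composition from the treatment. Single libraries mattered as well. The calls of MYC targets, integrated stress response, mitosis and NRF2 targets were lost without UNC0379 replicate 2 (medians -0.093, -0.19, 0.015 and -0.085). Those of the unfolded protein response, mitosis, NRF2 targets and histones were lost without DMSO replicate 1 (medians -0.38, -0.12, -0.12 and 0.068). Histones also lost the call without UNC0379 replicate 1 (median -0.49) and mitochondrial-encoded transcripts without DMSO replicate 2 (median -0.022).

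Single-gene calls after UNC0379 depended on the fit. Of 15 named genes called, RNU1-1 kept the call under every alternative and GDF15 lost it in 1 of 23. CDKN1A lost it in 10 of 23 (adjusted p up to 0.52), MSMO1 in 13 of 23, and HMGCS1, DDB2, SPATA18, TNFRSF10A and NDUFB9 in 13 of 22 each, with no change of direction. In all, 14 genes rose and 3 fell after UNC0379 (edgeR), and 2324 genes had an unadjusted p under 0.05, where 867 are expected by chance. Scaled by library totals the split was 5 higher and 0 lower, and DESeq2 called 115 higher and 65 lower. Besides the genes above, NECTIN4 rose from 0.49 ± 0.12 to 4.91 ± 1.36 CPM, INPP5D, an inositol phosphatase gene, from 0.68 ± 0.33 to 6.65 ± 3.02 CPM, and ACTA2, which encodes a smooth muscle actin, from 3.99 ± 2.89 to 31.1 ± 12.0 CPM. The U1 small nuclear RNA gene RNU1-1 rose from 5.67 ± 0.02 to 45.4 ± 2.96 CPM; it is 1 of several near-identical copies, so its level is uncertain. The genes that fell were VWA1, a matrix protein gene, the receptor gene NOTCH3 and NDUFB9, a subunit of respiratory complex I, with log2 fold changes of -1.79, -1.77 and -1.02. Without UNC0379 replicate 1, 509 genes rose and 305 fell, and without UNC0379 replicate 2, 3 rose and 0 fell.

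The responses to siRNA and compound overlapped in p53 targets. ACTA2, BTG2, CDKN1A, GDF15 and NECTIN4 rose in both comparisons, 5 genes where 0.18 are expected from independent lists (two-sided Fisher's exact test, p = 6.28e-07, genes not being independent). BTG2, CDKN1A and GDF15 are on the p53 target list, and ACTA2 and NECTIN4 are not. The calls of both comparisons also come from the same model with a shared estimate of spread, so the lists are not fully independent. The 5 became 0 without siSETD8 replicate 2 and with each comparison's own 4 libraries. They became 1 with limma-voom and without siCTR replicate 1, siSETD8 replicate 1 or DMSO replicate 2, and 76 without UNC0379 replicate 1. With 3 genes lower after UNC0379, 0.032 shared falls are expected by chance, so the 0 found says nothing. Of the 186 genes that fell after siSETD8, 139 had a negative log2 fold change after UNC0379, and of the 224 that rose, 144 had a positive one. Log2 fold changes of the 2 comparisons, which share no control library, correlated weakly across all 17331 genes (Pearson r = 0.27, Spearman rho = 0.21) and more across the 53 p53 targets (r = 0.62, rho = 0.58), of which 47 had the same sign. The correlation across all genes was 0.081 without siSETD8 replicate 2, 0.11 without UNC0379 replicate 2, 0.15 without siCTR replicate 1, 0.056 with no low-count filter and 0.46 with the covariate. The p53 target list did not pass the test of a difference between the responses (median 0.08, camera adjusted p = 0.79).

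**Figure D2:**
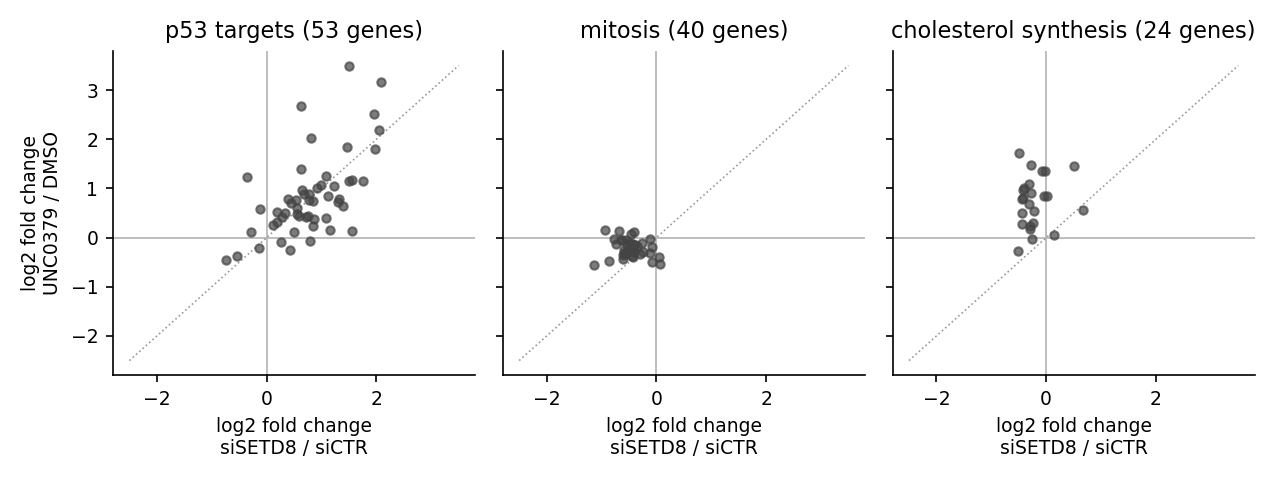
Log2 fold change after siSETD8 (horizontal axis) and after UNC0379 (vertical axis) of the genes of 3 lists, 1 point per gene, with equality as a dotted line. Of 53 p53 targets, 47 have the same sign in both comparisons, the 40 mitosis genes have medians of -0.47 and -0.26, and the 24 cholesterol synthesis genes have medians of -0.28 and 0.80.

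The difference between the responses passed for 7 genes in edgeR, 6 with the larger value after UNC0379. This count depended on the fit, with 392 in DESeq2, 602 with no low-count filter, 63 with the covariate and 1 to 81 without 1 library, and far more with a replicate block. KMT5A, HRAS, COMMD6 and SMIM14 fell after siSETD8 and had log2 fold changes between -0.23 and 0.23 after UNC0379, which gave differences of 2.81 (SE 0.26), 2.38 (SE 0.25), 2.04 (SE 0.23) and 2.13 (SE 0.29). RNU1-1 differed by 3.91 (SE 0.32). NRSN1, a neuronal membrane protein gene, differed by -1.83 (SE 0.25), with 10.4 ± 0.20 and 29.8 ± 2.88 CPM in siCTR and siSETD8 and 13.4 ± 0.41 and 10.9 ± 0.36 CPM in DMSO and UNC0379. RNU1-1 kept the call of a difference under every alternative, while KMT5A lost it in 2 of 22, HRAS in 4 of 21, COMMD6 in 4 of 22, SMIM14 in 8 of 20 and NRSN1 in 8 of 22. The cholesterol synthesis list differed by a median of 0.94 (camera, adjusted p = 7.2e-10, and adjusted p = 0.71 with an estimated correlation). The arms differ in time (36 h and 12 h) and in handling, which this contrast does not separate from the means of lowering SETD8.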

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

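The tests of the replicate ratio of antisense RNAs and of the level of the siCTR libraries were chosen only after the result was seen, as were the GC and length corrections and the split of the libraries in the 7-mer search. The 7-mer search had its threshold set before it was run.

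Genes that fell after siSETD8 but not after UNC0379 make up the first pattern: the difference of the log2 fold changes passed the test for KMT5A (2.81), HRAS (2.38), SMIM14 (2.13), COMMD6 (2.04) and PLCXD3 (1.79), the last outside the naming rule. After a correction for GC content and gene length the 5 differences were 1.77 to 2.79, so a smooth trend with either accounts for little of them. All 5 kept the call, but they were picked for passing it with large differences, so that alone tests little. In the wider set called lower after siSETD8, 166 of 186 kept theirs. That set is not this pattern alone, since 139 of the 186 had a negative log2 fold change after UNC0379 too. Matches to an siRNA seed in 3' UTRs passed a test that could have failed: the 7-mer GGAAGGA, present in the SETD8 coding sequence (GRCh37 chromosome 12, 123888160 to 123888166), as are 3358 of the 16346 searched, had t = -14.77 after siSETD8, the lowest of all, where the lowest after UNC0379 was -8.21 and GGAAGGA itself had 1.02. Picked as the lowest in siSETD8 replicate 1 against siCTR replicate 1, it was again the lowest in the other 2 libraries, t = -13.67, and the reverse split gave the same 7-mer and t = -18.27. A candidate explanation is that part of the falls comes from the siRNA acting on other transcripts and not from loss of SETD8, which stays a hypothesis because the siRNA sequence was not used here, and which leaves open the 55 genes that fell without the 7-mer, COMMD6 among them, and the difference in time between the arms.

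Antisense RNAs that rose after siSETD8 make up the second pattern, with 32 lncRNAs called that have a gene on the opposite strand. The share of reads on the wrong strand, from a count column outside the comparisons, was above the controls in the siSETD8 libraries (3.13% and 1.14%) and slightly above in the UNC0379 libraries (0.133% and 0.149%, against 0.118% and 0.113% with DMSO). If reads of the sense gene on the wrong strand were the source, the siSETD8 libraries should differ by the log2 ratio of their shares, 1.46, and the median over the 32 RNAs was 1.35. A limit was set for each RNA as all reads of its opposite-strand neighbours times the library's median wrong-strand share. Of the 32, 5 exceeded it in both siSETD8 libraries, so true antisense transcription stays open for these 5. Neighbours with a share above the median could also exceed it, and ENSG00000269888 had 33 reads against 31.8 in siSETD8 replicate 1. For the other 27 it cannot be told apart, since their counts lie within that limit in at least 1 siSETD8 library. One of the 5, PURPL, is a lncRNA known to be induced by p53. It lies outside the naming rule and was chosen after its values were seen. It had 29 and 53 reads in siCTR and 174 and 309 after siSETD8, against a limit of 0.

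Cholesterol synthesis genes, higher after UNC0379 than after siSETD8 by a median of 0.94, make up the third pattern. No single library decides the call, since the highest camera adjusted p over the 8 fits without 1 library was 5.46e-06, but the size after UNC0379 rests more on replicate 2 (median 0.80, and 0.49 without it). Those 8 fits all used the preset correlation of 0.01. The correlation estimated for this list was 0.49, and camera with an estimated correlation gave adjusted p = 0.71 for the difference. The 8 fits therefore speak only to the call under the preset. GC content or gene length is argued against for the rise after UNC0379, since the median after UNC0379 was 0.82 after the correction. The siCTR libraries were not already at the UNC0379 level, since the median log2 ratio of UNC0379 to siCTR was 1.23, with all 24 members above. The list was higher with DMSO than in siCTR and after UNC0379 than with DMSO, so this could hardly have come out otherwise. The ratio includes the difference between the controls and does not isolate an effect of UNC0379. Time, transfection and an action of UNC0379 apart from SETD8 were not tested and stay open, and the siCTR and DMSO libraries differed in this list by a median of 0.64.

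Other differences between the responses were RNU1-1 (3.91) and NRSN1 (-1.83). By list, the median difference was 0.44 for lysosome genes, 0.24 for mitosis genes, -0.21 for neuronal differentiation genes and -0.88 for 6 fibroblast markers. Without some single libraries the mitosis call was lost with medians from -0.072 to 0.21, while the neuronal and fibroblast calls were lost at medians of -0.26 to -0.20 and -0.92 to -0.71, near their main values. Calls lost among genes without the 7-mer were lysosome (median 0.39, camera adjusted p = 0.066), mitosis (median 0.28, adjusted p = 0.057) and neuronal differentiation (median -0.17, adjusted p = 0.061). Mitosis also lost the camera call in counts without regard to strand (median 0.26, adjusted p = 0.053) and with the GC and length correction (median 0.19, adjusted p = 0.084). Among genes without an opposite-strand gene all 4 calls were lost, with the neuronal median at -0.0018 and the others little changed (mitosis 0.26, fibroblast -0.86 and lysosome 0.49). With no low-count filter the fibroblast median was -0.16 and its call was lost. Reads in no gene were above the controls in both treated groups, at 22.6% and 30.5% after siSETD8 against 16.3% and 21.5% in siCTR, and at 14.9% and 23.3% after UNC0379 against 11.4% and 10.8% with DMSO.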

How the results depend on the processing

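Single genes were followed through the alternatives only in the comparison for which the naming rule took them. GDF15, ACTA2, SMIM14 and NRSN1 after siSETD8, for example, were not followed. No call that was followed changed direction, but calls were lost. Of 28 such calls after siSETD8 besides KMT5A, 3 (HRAS, COMMD6 and BTG2) held under every alternative. Of 15 after UNC0379, 1 (RNU1-1) held, and of 6 in the difference, 1 (RNU1-1). The tests lost were 118 of 618, 150 of 337 and 26 of 129. The fall of SETD8 kept its call throughout (log2 fold change -2.94 to -2.51 without 1 library). The p53 list kept its camera call in both comparisons under each alternative run for lists but the estimated correlation (adjusted p = 0.41 and 0.39, medians 0.77 and 0.73). So did mitosis after siSETD8 (-0.47) and cholesterol synthesis after UNC0379 (0.80) but for the estimated correlation (adjusted p = 0.55 each) and fry (0.19 and 0.15). Without 1 library the medians were 0.67 to 0.84, 0.45 to 0.86, -0.65 to -0.36 and 0.49 to 0.95. Counts of genes moved far more. Counts are given as higher and lower after siSETD8, higher and lower after UNC0379, differing, and higher in both; the main values are 224, 186, 14, 3, 7 and 5. DESeq2 gave 488, 448, 115, 65, 392 and 34. No low-count filter gave 767, 614, 479, 277, 602 and 102, and a correlation of fold changes of 0.056. Own 4 libraries gave 563, 521, 1, 0 and, for both, 0. limma-voom gave 3, 0 and 1 for UNC0379 and both, library totals 5, 0, 13 and 3 for UNC0379, the difference and both, and a minimum of 1 CPM in 2 libraries 5, 0 and 3. A minimum log2 fold change of 1 left 97 lower after siSETD8. Chosen after seeing the data, counts without regard to strand gave 95 higher after siSETD8. The GC and length correction gave 5, 1, 25 and 3 for UNC0379, the difference and both. The share of reads in no gene as covariate gave 72, 39, 2, 0, 63 and 1, and a correlation of 0.46. Genes without an opposite-strand gene gave 67 and 70 after siSETD8. Genes without the 7-mer gave 120, 52 and a difference of 3. The last 2 settings test fewer genes; for the others the cause was not tested.

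Without 1 library the ranges were 17 to 483, 7 to 458, 2 to 509, 0 to 305, 1 to 81 and 0 to 76, and the correlation was 0.081 to 0.35; the lone library of a group is assumed to vary like the others. The highest UNC0379 counts came without UNC0379 replicate 1, and the lowest siSETD8 counts without siCTR replicate 2 (17 higher) and siSETD8 replicate 2 (7 lower).

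The labels share only replicate numbers between groups. Deviations of same-numbered libraries correlated at 0.23 (siCTR and siSETD8) and 0.37 (DMSO and UNC0379), and at 0.046 to 0.44 between the arms, which share no control. A replicate block within each arm gave 1200, 1073, 569, 451, 1009 and 144, and a replicate block over all libraries 846, 799, 213, 81, 453 and 66.

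The direction of the camera test turned, with medians, for mitosis after UNC0379 without UNC0379 replicate 2 (0.015, range without 1 library -0.53 to 0.015) and with the covariate (0.091), DNA replication after UNC0379 (0.17), MYC and ribosome biogenesis after siSETD8 (-0.015) and NRF2 targets after UNC0379 (-0.0075) with the covariate, histones after UNC0379 without DMSO replicate 1 (0.068, range -0.67 to 0.068), and the mitosis difference without UNC0379 replicate 1 (-0.072, range -0.072 to 0.48). The -0.015 and -0.0075 kept the sign of the main medians. Among lists that passed camera, the median alone crossed 0 for apoptosis targets after UNC0379 among genes without an opposite-strand gene (-0.16) and for mitochondrial-encoded transcripts after UNC0379 without DMSO replicate 2 (-0.022) and with the covariate (-0.082). Depth limits low genes most: the smallest library held 16425693 gene reads.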

Other observations

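The control groups differed from each other in more genes than either treatment differed from its control. DMSO against siCTR gave 703 higher and 576 lower genes (edgeR). DNA replication genes were higher with DMSO (median 0.54, 8 of 39 rose, camera adjusted p = 9.9e-08), as were cholesterol synthesis genes (median 0.64, 5 of 24 rose, camera adjusted p = 1.7e-06) and mitosis genes (median 0.35, 4 of 40 rose, camera adjusted p = 0.00012). The p53 targets were lower (median -0.34, 10 of 53 fell and 1 rose, camera adjusted p = 0.00042). CDKN1A was at 97.6 CPM in siCTR and 29.2 CPM with DMSO (log2 fold change -1.74, SE 0.36, adjusted p = 0.022, edgeR). Each of these lists had adjusted p = 0.80 with an estimated correlation.

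Mitochondrial-encoded transcripts were lower with DMSO than in siCTR (median -2.27, 12 of 13 fell, camera adjusted p = 3.9e-10, and adjusted p = 0.80 with an estimated correlation). The imprinted gene DLK1 rose (log2 fold change 2.95, SE 0.49, adjusted p = 0.0099, edgeR), a gene chosen after its values were seen.

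In the p53 list after siSETD8, the 21 members with GGAAGGA in the 3' UTR had a median log2 fold change of 0.63 and the 32 without it 0.83. A seed match would lower the genes that hold it. This split therefore cannot show whether an action of the siRNA on other transcripts raised the list indirectly. For mitosis the medians were -0.53 over 4 members with it and -0.46 over 36 without it.

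Lists that did not pass camera after siSETD8 were DNA damage repair, H4K20 methylation enzymes and readers (median 0.14 but mean -0.16), noradrenergic, mesenchymal and neuronal differentiation genes, cholesterol synthesis, integrated stress and unfolded protein responses, interferon, heat shock, hypoxia, NRF2, fibroblast, Schwann and glial, and epithelial markers, with adjusted p from 0.051 to 0.62. The last 2 lists had 2 tested members each, with highest levels of 1.96 and 2.11 CPM. The H4K20 list holds KMT5A itself (log2 fold change -2.69), the target of the siRNA, which lowers its mean.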
